A study of Mus musculus with 9 samples.

How the data were processed

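Total RNA of 9 samples of mouse pro-B cells was labelled with Cy3 and read in 1 colour on 9 Agilent 4x44K mouse arrays. The cells were transformed with the Abelson virus and carries a conditional Ebf1 allele with a tamoxifen-inducible Cre recombinase, so that 4-hydroxytamoxifen deletes the endogenous gene. Groups were taken from the sample titles: 3 Mock arrays, 3 EBF1wt arrays and 3 EBF1ΔC arrays. The labels do not say whether replicates were separate cultures. If they were not separate, the p-values measure only the spread between these samples. One label note calls the retroviral transfer transfection while the others call it transduction, and the source name of EBF1wt replicate 3 leaves out tamoxifen, which its description mentions; that array was kept in its group.

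The values used are the intensity of each spot as processed by Agilent Feature Extraction, per the file headers a background-subtracted and detrended signal that was not normalized between arrays. Raw spot and local background intensity from the same deposited files served for an alternative. The headers name Feature Extraction 10.5.1.1, whereas the authors' processing notes name 9.1. The authors also deposited a second set of log2 values, whose normalization is not stated. Its columns correlated with quantile-normalized log2 spot signal plus an offset of 50 at Pearson r between 0.999 and 1.00 across probes, which are not independent replicates, and they were used as an alternative. Probe positions are those of the files (mm9, NCBI37).

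Of 45018 spots per array, 43379 were not controls and held 41174 probes. The log2 signal was taken relative to the 75th percentile of each array, spots marked as outliers by the scanner software were left out (73 to 163 per array), and spots of the same probe were averaged. A probe was kept if it was well above background on all 3 arrays of at least 1 group, which left 22357 probes, 19976 of them with a gene. Probes were named from the RefSeq gene reference by accession (27479), symbol (5455) or synonym (666), or kept the name in the files (1142), and 6432 had no gene. The probe with the highest mean over the 9 arrays stood for its gene, giving 11989 genes. Among the 5358 genes with more than 1 probe, probes of 40 genes were called in opposite directions between EBF1wt and Mock, of 39 between EBF1ΔC and Mock, and of 0 between EBF1ΔC and EBF1wt.

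All 9 arrays entered 1 linear model with a mean per group in limma 3.58.1 (R 4.3.3, data.table version 1.17.8, statmod version 1.5.0), with 6 residual degrees of freedom and moderated two-sided tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Changes are log2 differences with the standard error (SE) of the model, and group values are means with the standard deviation (SD) over 3 arrays. Where 1 group was not well above background on any array, the fold is a lower bound. For the bound, the values of that group were raised to the lowest value well above background on each array. No fold is given where both groups were below background or the bound did not exceed 1.

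The 22 gene lists were the pre-BCR and BCR complex and proximal signalling, B-lineage transcription factors, V(D)J recombination and end joining, pro-B surface receptors and adhesion, mature B cells, plasma cells, T, NK and innate lymphoid cells, myeloid cells, stem and multipotent progenitor cells, erythroid and megakaryocytic cells, stromal cells, DNA replication, mitosis, apoptosis regulators, p53 target genes, interferon response, MYC and ribosome biogenesis, glycolysis, cholesterol synthesis, cytokine receptor and JAK-STAT feedback, immediate early genes, and DNA methylation and SWI/SNF chromatin remodelling. Each was tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists in a comparison, and again with an estimated correlation. The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. That rule took Ebf1 and 17 B-lineage and lymphoid genes. It added, per comparison, the 8 highest and 8 lowest called genes measured well above background on all arrays of both groups without overlap and bearing a proper gene symbol. It also took the 4 largest bounds in each direction and up to 4 called members of each list, and up to 2 as values where none was called.

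Left out were probes without a gene name from all gene counts, and control spots. Alternatives were normexp background correction with quantile normalization, quantile normalization alone, scaling to the median, the authors' values, other filters, slide or replicate number as a block, array weights, trended and robust moderation, the mean of the probes of a gene, other thresholds, a fit of only the 2 groups compared, and leaving out each array. For lists, fry was also run. A random slide block between EBF1ΔC and EBF1wt, and a restriction to genes well above background in a compared group, were added after seeing the data. The procedure was tested on simulated data in which 50 genes per fold of 11989 were changed. Of those changed 2-fold, 52%, 44% and 46% were called in the comparisons EBF1ΔC with EBF1wt, EBF1wt with Mock and EBF1ΔC with Mock, and of those changed 3-fold 96%, 94% and 96%, with 4, 2 and 5 false calls. A shifted list of 20 genes was found with either correlation, and 0 other lists. The simulated noise was independent between genes, so this does not test the preset correlation on genes that vary together.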

Results

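Gene expression was measured in Abelson-virus-transformed pro-B cells after the deletion of Ebf1, a transcription factor that specifies the B lineage, and its replacement by retroviral EBF1. Mock cells received no EBF1 and were harvested 4 days after 2 µM 4-hydroxytamoxifen, ahead of cell death. EBF1wt cells received the full-length protein and EBF1ΔC cells a protein without the C-terminal domain; both were given tamoxifen 24 h after transduction, sorted for GFP 5 days later and used after more than 2 further weeks. Each group had 3 arrays, a number that limits the precision. Between 54.3% and 56.9% of probes were well above background on Mock arrays, between 50.7% and 51.2% on EBF1wt arrays and between 51.4% and 53.4% on EBF1ΔC arrays. The 75th percentile of the signal ran from 384 to 507.7 intensity units. The first principal component held 74.6% of the variance and set Mock (-74.2 to -80.6) apart from both EBF1 groups (35.8 to 42.2), and the second held 12.5% and parted EBF1wt (12.8 to 45.8) from EBF1ΔC (-22.6 to -31.4). EBF1wt replicate 2 stood apart from its group on the second component (45.8, against 12.8 and 15.2) and had the lowest array weight (0.372, against 1.35 for each of the others), followed by EBF1ΔC replicate 3 on the same slide (0.502). The Mock arrays shared a scan day and slides with no other group, so every comparison with Mock also differs by scan day, slide, time after tamoxifen, transduction and sorting.

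Ebf1 transcript was higher in both replaced groups than in Mock, by the probe for its mRNA (chromosome 11, 44818365 to 44818424). The log2 signal was 1.45 ± 0.28 in Mock, 3.06 ± 0.17 in EBF1wt and 3.80 ± 0.06 in EBF1ΔC (SD, n = 3 arrays). EBF1wt lay 3.05-fold above Mock (adjusted p = 3.46e-05, limma) and EBF1ΔC 5.10-fold above it (adjusted p = 5.08e-06). EBF1ΔC exceeded EBF1wt by 0.74 log2 (adjusted p = 0.0188), short of 2-fold, and by 0.99 and 0.66 within the 2 slides that held both groups. A second Ebf1 probe, designed on a cDNA clone (chromosome 11, 44462618 to 44462677), was well above background on Mock arrays alone and gave -3.61 and -3.87 log2 against Mock. Averaging both probes turned the Ebf1 change to -1.0 in EBF1wt and -0.76 in EBF1ΔC. Whether either probe lies in the deleted part of the gene or in the retroviral transcript is not known, so these values measure neither deletion nor transgene level.

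**Figure D1:**
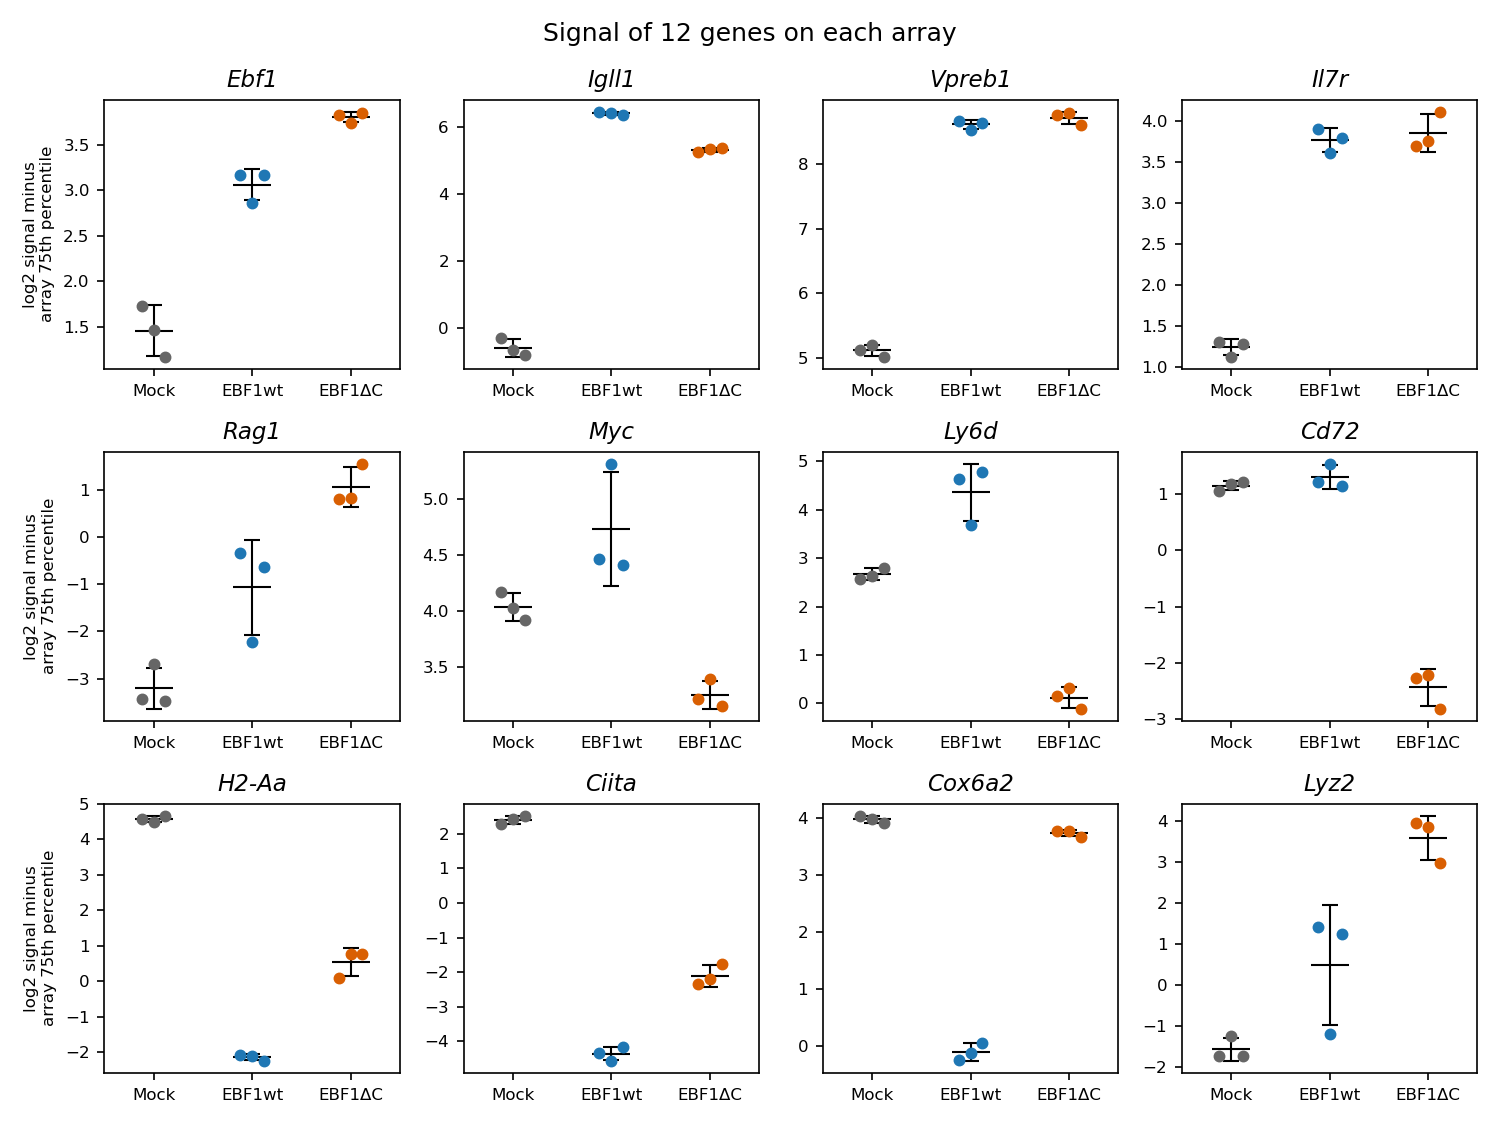
Log2 signal relative to the 75th percentile of the array (vertical axis, a separate scale in each panel) for named genes in Mock, EBF1wt and EBF1ΔC. Points are arrays, the horizontal line is the mean of 3 and the bar its SD; Igll1 is near 6.39 in EBF1wt, 5.32 in EBF1ΔC and -0.58 in Mock.

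The comparison of EBF1ΔC with EBF1wt asks what the C-terminal domain contributes, both groups having been transduced, sorted and cultured alike. The Ebf1 mRNA probe was 0.74 log2 higher in EBF1ΔC, however, so the differences are not assigned to the domain alone. EBF1ΔC cells had lower Cd72, an inhibitory B-cell surface receptor, Ly6d, a surface marker of B-lineage progenitors, and Igll1, the lambda5 surrogate light chain. They had higher MHC class II genes (H2-Aa, H2-Eb1) and Ciita, the transactivator of these genes, and higher Rag1, a component of the V(D)J recombinase. Also higher were Lyz2, the lysozyme of myeloid cells, and Lyz1, another lysozyme gene. Most of the B-lineage genes chosen beforehand differed little. In all, 330 of 11989 genes were called, 171 higher and 159 lower in EBF1ΔC, and 1093 passed the adjusted p alone.

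Cd72 fell by 3.74 log2 (SE 0.17, adjusted p = 1.76e-05), Ly6d fell by 4.24 (SE 0.26, adjusted p = 8.25e-05; chromosome 15, 74592551 to 74592610) and Asb2, a subunit of a ubiquitin ligase, fell by 5.37 (SE 0.45, adjusted p = 0.000408). Other low genes, ranked among called genes well above background on all arrays of both groups, were Col26a1 (-4.22), Slpi (-4.14), Ttll11 (-3.58), Galnt14 (-3.34, adjusted p = 1.99e-07) and Bhlha15 (-3.32). The highest under the same limit was Cox6a2, a cytochrome c oxidase subunit, 3.84 log2 above EBF1wt (SE 0.09, adjusted p = 2.57e-07; chromosome 7, 135349160 to 135349219). It was followed by Lyz2 (3.11, SE 0.63), Lyz1 (3.0, SE 0.63), Rgs10 (2.69), H2-Aa (2.68, SE 0.17; chromosome 17, 34421285 to 34421344), Tusc1 (2.67), Iigp1 (2.61) and Il10ra (2.51). Sparc was at least 9.37-fold, Epha2 at least 6.82-fold, Zfp831 at least 4.10-fold and Fam183b at least 4.05-fold higher. Tmem40 was at least 32.0-fold, Tmem132e at least 31.8-fold, Apbb1 at least 12.5-fold and Fetub at least 10.4-fold lower. Without EBF1ΔC replicate 1 or 2 the calls of Lyz2 (2.93 and 2.98), Lyz1 (2.86 and 2.87) and Zfp831 (2.84 and 2.63) were lost. Without EBF1wt replicate 2 they stayed called but the changes shrank to 2.27 for Lyz2, 2.13 for Lyz1 and 2.0 for Zfp831, and without EBF1ΔC replicate 3 Asb2 fell by 4.77.

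Among the genes chosen beforehand, Igll1 fell by 1.08 log2 (SE 0.12, adjusted p = 0.00167; chromosome 16, 16861104 to 16861163) and Rag1 was 2.14 higher (SE 0.47, adjusted p = 0.0289), by 3.79 and 1.46 within the 2 slides. The Rag1 call was lost without Mock replicate 3 (2.14) and without EBF1ΔC replicate 1 (2.27), 2 (2.26) or 3 (1.90), and without EBF1wt replicate 2 the change was 1.56. Values without a call were 1.00 for Id2 and -0.95 for Irf4, both just short of 2-fold, and they were called without EBF1wt replicate 1 (1.06 and -1.07), without EBF1wt replicate 3 for Id2 (1.1), without EBF1ΔC replicate 3 for Id2 (1.05) and without EBF1ΔC replicate 1 for Irf4 (-1.08). Further such values were 0.27 for Blnk, 0.17 for Cd79a, -0.11 for Cd79b, 0.10 for Vpreb1, 0.08 for Il7r, 0.06 for Foxo1, -0.12 for Pou2af1 and -0.17 for Pax5, and 0.003 for Vpreb3. Blk was below background in both groups, and Gata3 and Tcf7 were not among the genes tested.

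None of the 8 lists that passed camera held with an estimated correlation. Interferon response genes were higher as a list in EBF1ΔC (median 0.52, camera adjusted p = 1.03e-07, and adjusted p = 0.127 with an estimated correlation), with 2 of 18 members called higher, Usp18 (1.25) and Gbp2 (1.24). Usp18 lost its call without EBF1ΔC replicate 3 (1.0), and Gbp2 without EBF1wt replicate 2 (0.94) or EBF1ΔC replicate 1 (1.22). Mature B cell genes were also higher (median 0.34, camera adjusted p = 0.000177, and adjusted p = 0.127 estimated), with 5 of 20 called higher and 1 lower, among them H2-Aa, H2-Eb1 (2.37), Ciita (2.25) and Cd38 (1.49). T, NK and innate lymphoid cell genes were higher (median 0.67, camera adjusted p = 0.00091, and adjusted p = 0.213 estimated) with 3 of 12 called, including Klrd1 (1.33) and Lck (1.28), the T-cell receptor kinase. Lck lost its call without EBF1wt replicate 2 (0.89), Mock replicate 3 (1.28) or EBF1ΔC replicate 1 (1.28), 2 (1.27) or 3 (1.30); Nkg7 was below background in both groups. Cytokine receptor and JAK-STAT feedback genes were higher (median 0.14, camera adjusted p = 0.00765, and adjusted p = 0.213 estimated) with 1 of 16 called, Il4ra (1.41), and erythroid genes (median 0.60, camera adjusted p = 0.0365, and adjusted p = 0.213 estimated) with 0 of 4 called. MYC and ribosome biogenesis genes were lower (median -0.29, camera adjusted p = 8.63e-07, and adjusted p = 0.235 estimated), with 1 of 18 called, Myc itself (-1.48). Plasma cell genes were lower (median -0.30, camera adjusted p = 0.00619, and adjusted p = 0.127 estimated) with 2 of 5 called, Jchain (-1.28) and Fkbp11 (-1.10, and -0.85 without EBF1wt replicate 2 or -0.99 without EBF1ΔC replicate 1, where its call was lost), and the pre-BCR list was lower (median -0.16, camera adjusted p = 0.0365, and adjusted p = 0.304 estimated) with 2 of 22 called, Cd72 and Igll1. The pre-BCR call was lost without EBF1wt replicate 1 (median -0.10) or 3 (-0.04) or EBF1ΔC replicate 3 (-0.17) and with slide as a block. The erythroid call was lost without EBF1wt replicate 3 (0.58) or EBF1ΔC replicate 2 (0.53), and with the authors' values, quantile normalization with or without normexp, other filters, slide as a block, and trended and robust moderation. Relative to all genes, the T and NK median shrank from 0.67 to 0.14 with the authors' values and 0.16 with normexp, the erythroid one from 0.60 to 0.09 and 0.12, the interferon one from 0.52 to 0.32 and 0.33, and the mature B one from 0.34 to 0.21 with either. The pre-BCR median was -0.07 with normexp.

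The other 14 lists passed camera in neither direction. V(D)J recombination had 2 of 11 members called higher, Rag1 and Dntt (1.51), at an adjusted p of 0.476; Dntt lost its call without EBF1wt replicate 2 (1.39) or 3 (1.47). Pro-B receptors had 2 of 17 higher, including Itgal (1.72), and 2 lower, Ly6d and Il2ra, at 0.623. Il2ra was well above background on 0 EBF1ΔC arrays and 1 EBF1wt array, so no fold is given, and its call was lost on leaving out any array but EBF1wt replicate 3. Immediate early genes had Jun higher (1.19) and Nr4a1 lower (-1.47, and -1.49 or -1.43 without EBF1ΔC replicate 1 or 2, where its call was lost), at 0.722. Single members called higher were Lyz2 of 11 myeloid genes (0.0734), Sparc of 4 stromal genes (0.161), Bmf (1.00) of 19 apoptosis regulators (0.89) and Pltp (1.08) of 17 p53 targets (0.556). Bmf lost its call without EBF1wt replicate 2 (0.91) or EBF1ΔC replicate 2 (0.99) or 3 (1.0). Without EBF1wt replicate 2 the myeloid list passed (median 0.18), and without EBF1ΔC replicate 1 the glycolysis list did (-0.30). The lists of B-lineage transcription factors (0.887), stem cells (0.175), DNA replication (0.722), mitosis (0.566), glycolysis (0.0886), cholesterol synthesis (0.462) and DNA methylation and SWI/SNF (0.89) had 0 called members. Adjusted over the list alone, the counts of all 22 lists were the same except for pro-B receptors, with 3 higher. The test pointed up while the median was below 0 for immediate early genes (median -0.21, mean -0.17), B-lineage transcription factors (-0.03, mean 0.06) and apoptosis regulators (-0.01, mean 0.05).

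The median difference of genes called higher and lower was 2.03 and -2.09 on slide 4 and 1.36 and -1.41 on slide 5; all 330 had been called on these arrays without overlap between the groups, which fixes the direction within a slide, so this is no test of slide. With slide as a fixed block, which leaves 2 residual degrees of freedom, 146 genes were called (73 in each direction, 123 of them also called without the block), and 22 of the 46 named genes called here lost the call. These were Bmf, Cd38, Dntt, Fkbp11, Gbp2, Igll1, Iigp1, Il2ra, Itgal, Jun, Klrd1, Lck, Myc, Nkg7, Nr4a1, Pltp, Rag1, Rgs10, Ttll11, Tusc1, Usp18 and Zfp831. The authors' values gave 125 calls and ended those of Bmf, Ciita, Epha2, Fam183b, Fkbp11, Il2ra, Il4ra, Jchain, Nkg7, Usp18 and Zfp831, with Pltp turned to -0.12. A fit of only the 2 groups ended 14 of the 46, Rag1, Lyz1, Lyz2 and Dntt among them, and the mean of the probes ended that of Igll1.

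Against Mock, EBF1wt cells had much higher surrogate light chain genes (Igll1, Vpreb1, Vpreb2), Il7r, the receptor for interleukin 7, and Rag1. They had lower MHC class II genes, Ciita and many other genes of mature B cells, and lower embryonic and adult beta-globins. The comparison addresses the effect of restoring full-length EBF1 to cells that lost it, along with the differences in time, handling and slides named above. Of 11989 genes 2322 were called, 791 higher and 1531 lower.

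Igll1 was 125-fold higher in EBF1wt (6.97 log2, SE 0.12, adjusted p = 7.48e-09), Vpreb2 25.9-fold, Vpreb1 11.3-fold (3.50 log2, SE 0.08), Il7r 5.80-fold (2.54 log2, SE 0.13), Rag1 4.40-fold (2.14 log2, SE 0.47), Vpreb3 2.83-fold, Foxo1 2.58-fold, Irf4 2.17-fold and Cd79b 2.11-fold. Without EBF1wt replicate 2, Irf4 (0.99) lost its call. Changes short of 2-fold were 0.78 for Cd79a, 0.40 for Blnk, 0.25 for Pax5, 0.12 for Pou2af1 and -0.41 for Id2. Scaling to the median carried Cd79a and Blnk past 2-fold. Blk was at least 5.02-fold lower. Among genes well above background on all arrays of both groups, the highest besides Igll1 were Ttll11 (7.61), Rnf130 (5.91), Cd248 (5.45), Ell3 (5.24), Nyx (5.24), Col26a1 (5.24) and Tmed3 (5.22). The lowest under the same limit were Hbb-bh1 (-7.51, SE 0.75; -6.79 without EBF1wt replicate 2), Ciita (-6.77, SE 0.16), H2-Eb1 (-6.73), H2-Aa (-6.72, SE 0.17), Hbb-bt (-6.53), Gpr183 (-6.51), Gimap4 (-6.39) and Ackr2 (-6.39). Maoa was at least 55.9-fold, Gfra2 at least 33.8-fold, Tmem40 at least 32.8-fold and Tmem132e at least 32.5-fold higher. Cd300lf was at least 84.4-fold and Tlr7 at least 68.3-fold lower.

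Mature B cell genes fell in EBF1wt, with 13 of 20 members called lower and 0 higher (median -2.28, camera adjusted p = 2.87e-08, and 0.0326 with an estimated correlation), and Fcer2a was at least 54.4-fold lower. No other list held with an estimated correlation. Cholesterol synthesis genes were lower (10 of 18 called, median -1.01, camera adjusted p = 9.17e-07, and adjusted p = 0.396 with an estimated correlation), among them Mvd (-2.26) and Hmgcs1 (-1.63). Interferon response genes were lower (9 of 18, median -1.19, camera adjusted p = 1.33e-05, and adjusted p = 0.221 with an estimated correlation), as Oasl2 (-2.74) and Stat2 (-1.47). Cytokine receptor genes were lower (6 of 16 lower and 1 higher, median -0.93, camera adjusted p = 0.00229, and adjusted p = 0.243 estimated), with Il4ra (-4.59) and Bcl6 (-3.36) lower and Ccnd3 (2.07) higher. Myeloid genes were lower (6 of 11 lower and 2 higher, median -1.17, camera adjusted p = 0.0194, and adjusted p = 0.221 estimated), with Tyrobp (-4.92) lower, Itgax at least 31.5-fold lower and Cebpb (3.57) higher. T and NK cell genes (4 of 12 lower and 1 higher, camera adjusted p = 0.0194, and adjusted p = 0.363 estimated), glycolysis genes (4 of 19 lower and 1 higher, camera adjusted p = 0.0402, and adjusted p = 0.527 estimated) and erythroid genes (3 of 4 lower, camera adjusted p = 0.046, and adjusted p = 0.319 estimated) were lower too. Slc2a3 (-5.87), a glucose transporter, was the lowest of the glycolysis list. The glycolysis call was lost without Mock replicate 1 or EBF1wt replicate 1 or 3 (medians -0.02, -0.09 and -0.09), and the erythroid call without Mock replicate 1 or EBF1wt replicate 2 or 3 (-2.21, -2.20 and -2.03). Among genes well above background on all 9 arrays the erythroid median turned to 0.53. The authors' values and quantile normalization ended the T and NK and erythroid calls, median scaling the glycolysis call, and the mean of the probes the myeloid and erythroid calls.

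Proliferation lists were higher in EBF1wt: mitosis (1 of 22 called, median 0.58, camera adjusted p = 9.61e-05, and adjusted p = 0.314 estimated), DNA replication (2 of 22, median 0.53, camera adjusted p = 0.0194, and adjusted p = 0.527 estimated) and MYC and ribosome biogenesis (0 of 18, median 0.54, camera adjusted p = 0.0211, and adjusted p = 0.527 estimated). The MYC call was lost without EBF1wt replicate 2 (median 0.41), and it and the DNA replication call were lost with the authors' values and with quantile normalization. Pre-BCR genes went both ways (6 of 22 higher, 4 lower, camera adjusted p = 0.182), as did B-lineage transcription factors (7 of 22 higher, 2 lower, camera adjusted p = 0.411), with Myb (2.60) and Lef1 (1.97) higher and Mef2c (-2.35) and Ikzf1 (-1.87) lower. V(D)J recombination had 3 of 11 higher and 1 lower (camera adjusted p = 0.321), plasma cells 1 of 5 each way (0.684), with Jchain lower (-5.76), apoptosis regulators 1 of 19 higher, Bcl2l1 (1.74; 0.451), and DNA methylation and SWI/SNF 1 of 18 higher (0.107). The pro-B receptor list had 6 of 17 higher and 5 lower with a median of 0.43, a mean of -0.19 and a test pointing up. Stem cell genes (3 of 7 lower, median 0.11, mean -0.84), p53 targets (4 of 17 higher and 2 lower, 0.10, mean -0.01) and immediate early genes (4 of 15 each way, 0.57, mean -0.09) had a test pointing down, and stromal genes (0 of 4, -0.05, mean -0.07) one pointing up. Adjusted over the list alone, the counts of all 22 lists were the same.

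Of 92 named genes called here, 22 lost the call with the authors' values, Irf4, Blk and Oasl2 among them, and 22 with normexp and quantile normalization, Irf4, Cd79b, Blk and Oasl2 among them. Median scaling ended 7, Hmgcs1 and Stat2 among them. Scaling to the median raised the median change of all genes from 0.12 to 0.83 log2 in this comparison, from 0.11 to 0.65 between EBF1ΔC and Mock, and moved it to -0.16 between EBF1ΔC and EBF1wt. The share of calls that were higher against Mock rose from 34.1% to 85.3% in EBF1wt and from 35.1% to 78.5% in EBF1ΔC, and it was 45.4% and 44.4% after quantile normalization, so the balance of higher and lower genes depends on the scaling. Relative to the median of all genes, mature B cell genes lay between -2.40 and -1.47 in EBF1wt under the 5 scalings. With normexp and the authors' values, interferon genes shrank from -1.31 to -0.59 and -0.56, myeloid genes from -1.29 to -0.43 and -0.45, and erythroid genes from -2.27 to -0.43 and -0.36.

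EBF1ΔC cells also had much higher Igll1, Vpreb1, Vpreb2, Il7r and Rag1 than Mock, and lower MHC class II, globin and mature B cell genes. This comparison addresses the effect of restoring EBF1 without its C-terminal domain, with the same differences in time, handling and slides. It gave 2165 called genes, 760 higher and 1405 lower.

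Igll1 was 59.4-fold higher (5.89 log2, SE 0.12, adjusted p = 1.85e-08), Vpreb2 21.0-fold, Rag1 19.4-fold (4.28 log2, SE 0.47), Vpreb1 12.1-fold, Il7r 6.13-fold, Vpreb3 2.84-fold and Foxo1 2.68-fold. Cd79b (0.96), Cd79a (0.94), Blnk (0.66), Id2 (0.59), Irf4 (0.17), Pax5 (0.09) and Pou2af1 (-0.001) did not reach 2-fold with scaling to the 75th percentile, except Cd79a without Mock replicate 1 (1.1). Scaling to the median, which moved the median change of all genes from 0.11 to 0.65, carried Cd79b, Cd79a, Blnk and Id2 past 2-fold. Blk was at least 5.30-fold lower. Among genes well above background on all arrays of both groups, the highest besides Igll1 were Nyx (6.24), Rnf130 (5.76), Lyz1 (5.45), Lyz2 (5.17), Cnksr3 (4.95), Tmed3 (4.45) and Vpreb2 (4.39). Among the lowest under the same limit were Ackr2 (-7.32), Gpr183 (-7.24), Hbb-bh1 (-7.24; -7.85 and -6.48 without EBF1ΔC replicate 2 or 3), Jchain (-7.04), Pcp4 (-6.84), Hbb-bt (-6.75) and Serpinb6b (-5.72). Prodh and Tusc1 were at least 49.9-fold, Camk4 at least 37.2-fold and Adgra3 at least 25.3-fold higher, and Cd5l at least 96.8-fold, Tlr7 at least 72.2-fold and Bcl2a1b at least 57.9-fold lower.

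Mature B cell genes fell here too, with 13 of 20 called lower (median -2.07, camera adjusted p = 7.92e-08, and 0.0376 with an estimated correlation), among them Ciita (-4.52), H2-Eb1 (-4.36) and H2-Aa (-4.03). The other 5 lists past camera were lost with an estimated correlation. These were cholesterol synthesis (11 of 18 lower, median -1.12, camera adjusted p = 1.5e-07, and adjusted p = 0.448 estimated), mitosis (higher, 1 of 22 called, median 0.56, camera adjusted p = 0.000121, and adjusted p = 0.389 estimated), glycolysis (4 of 19 lower and 1 higher, median -0.38, camera adjusted p = 0.00265, and adjusted p = 0.47 estimated), cytokine receptors (5 of 16 lower and 1 higher, median -0.86, camera adjusted p = 0.00582, and adjusted p = 0.389 estimated) and DNA replication (higher, 2 of 22 called, median 0.47, camera adjusted p = 0.00687, and adjusted p = 0.48 estimated). Interferon response genes, with 3 of 18 called lower (median -0.46), missed the threshold at a camera adjusted p of 0.0676, as did myeloid genes (5 of 11 lower and 2 higher, 0.0607). B-lineage transcription factors had 6 of 22 higher, with Erg (3.17) and Myb (2.51), and 3 lower, with Mef2c (-2.32), at 0.553. The remaining lists passed in neither direction: pre-BCR (4 of 22 higher and 5 lower, 0.553), with Cd22 (-3.64) lower, V(D)J recombination (3 of 11 higher and 1 lower, 0.167), pro-B receptors (5 of 17 higher and 4 lower, 0.722), with Cxcr4 (2.52) higher and Ly6d (-2.54) lower, plasma cells (1 of 5 higher and 2 lower, 0.267), T and NK cells (2 of 12 higher and 4 lower, 0.688), stem cells (1 of 7 higher and 2 lower, 0.553), erythroid cells (1 of 4 higher and 3 lower, 0.107), stromal cells (1 of 4 higher, 0.484), apoptosis (1 of 19 each way, 0.603), p53 targets (4 of 17 higher and 1 lower, 0.979), MYC (0 of 18, 0.722), immediate early genes (3 of 15 higher and 2 lower, 0.673) and DNA methylation and SWI/SNF (1 of 18 higher, 0.107). Of 91 named calls, 20 were lost with the authors' values and 19 with normexp and quantile normalization, Blk and Cd28 among them, and these values and quantile normalization also ended the DNA replication call. Adjusted over the list alone, the counts of all 22 lists were the same. Median and mean differed in sign for pro-B receptors (0.31 and -0.14), stem cell genes (0.07 and -0.53) and immediate early genes (0.33 and -0.26), and the test pointed down for p53 targets (0.06 and 0.07) and apoptosis regulators (median 0.03).

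**Figure D2:**
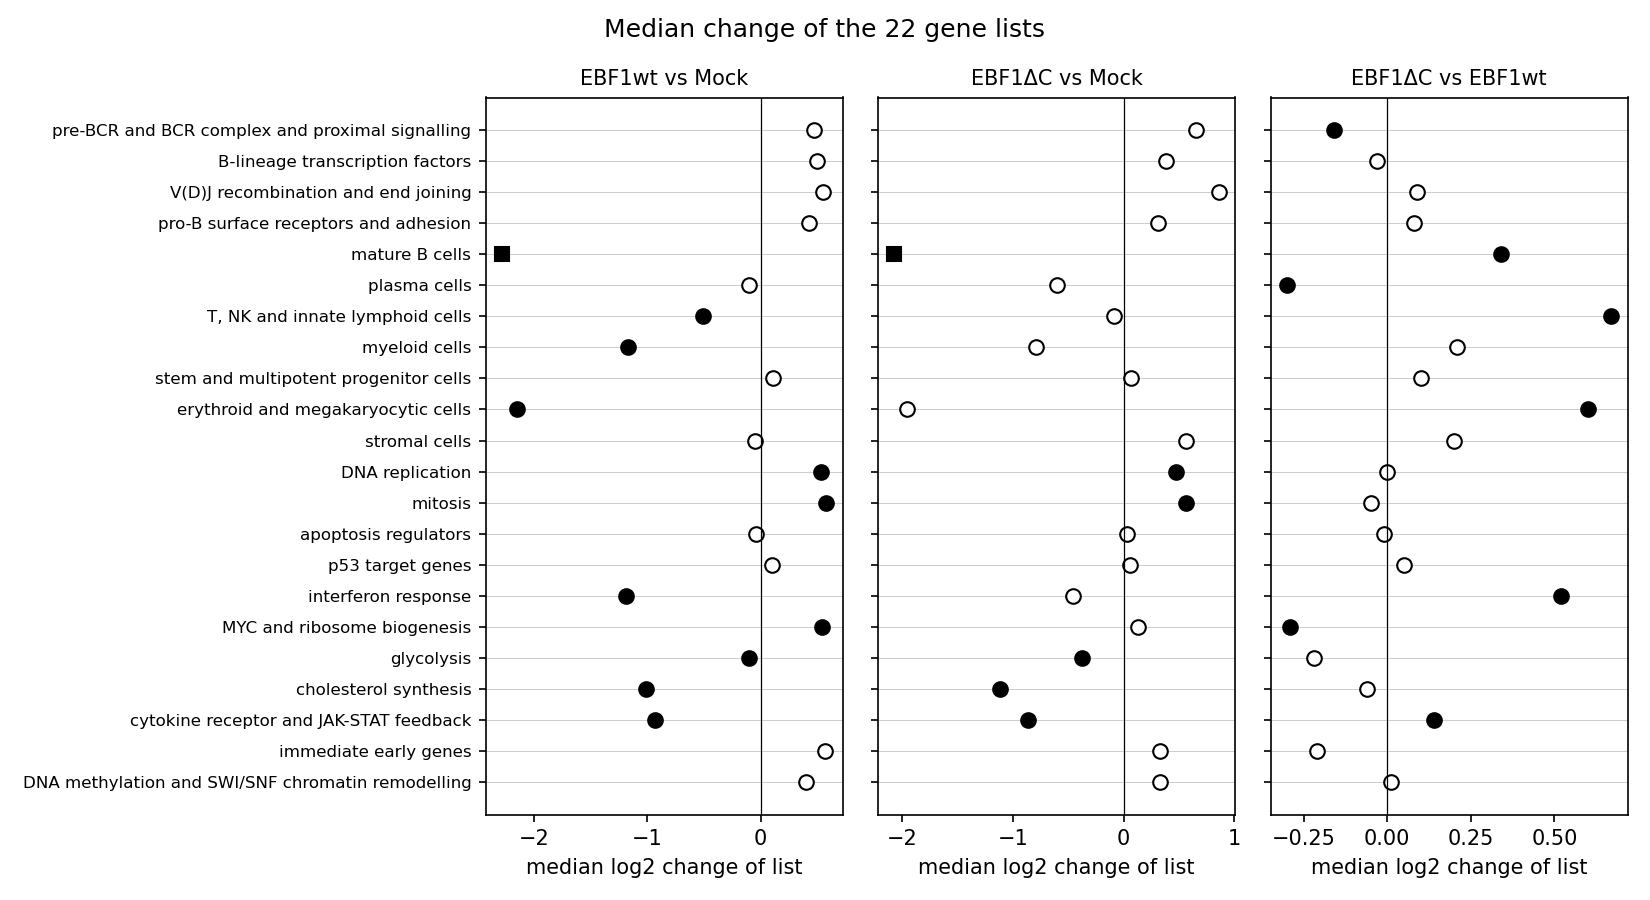
Median log2 change of each of the 22 gene lists (horizontal axis, scales differ between panels) in the 3 comparisons. Filled symbols passed camera at an adjusted p under 0.05 with the preset correlation and squares also with an estimated one, which only mature B cells did, at -2.28 and -2.07 against Mock.

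Differences from Mock were largely shared by both replaced groups, and a minority of these genes differed between EBF1ΔC and EBF1wt. Scan day, slide, time, transduction and sorting also separate both groups from Mock, so the shared part is not assigned to EBF1. Of the 791 genes higher in EBF1wt than in Mock, 73 (9.23%) were called lower in EBF1ΔC than in EBF1wt, among them Igll1, Ly6d, Cd248, Ell3, Col26a1, Ttll11 and Apbb1, and 19 were called higher still. Of the 1531 lower genes, 96 (6.27%) were called higher in EBF1ΔC, among them Cox6a2, H2-Aa, Ciita, Cd38 and Bcl3, and 22 lower still. The counts depended on the processing: they were 36 and 24 with normexp and quantile normalization, 35 and 25 with the authors' values, 40 and 51 with slide as a block and 125 and 61 with median scaling. Independent lists of these sizes would share 10 and 21.8 genes, a value that ignores the EBF1wt arrays common to both comparisons. In 100 simulated groups unchanged from EBF1wt there were at most 0 and 1, which covers false calls alone, so neither is a full measure of the overlap by chance. Summed over the genes, the change in EBF1ΔC was 0.877 times that in EBF1wt for higher genes (SD 0.0097 over EBF1ΔC arrays) and 0.889 times for lower genes (SD 0.021). The simulated ratio averaged 1 and reached at most 1.01. Those groups were drawn around the same EBF1wt means that chose the genes, which fixes the ratio near 1. It therefore leaves out the effect of choosing the genes on these arrays and is no test of the ratios. When responsive genes were chosen without 1 EBF1wt array and the change in EBF1wt was taken from that array alone, the ratio was 0.845 to 0.999 for higher and 0.894 to 0.943 for lower genes. Within slides 4 and 5 it was 0.912 and 0.862 for higher genes and 0.823 and 0.924 for lower genes.

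Both replaced groups shared 555 genes higher and 1176 lower than Mock, where independent lists would share 50.1 and 179. Since both comparisons use the same 3 Mock arrays, part of the excess can arise from those controls. In 100 simulated groups unchanged from Mock at most 0 and 1 genes were shared, which again covers false calls alone. A further 120 of the 330 genes that differed between EBF1ΔC and EBF1wt were not called between EBF1wt and Mock (56 higher and 64 lower in EBF1ΔC), Cd72 among them.

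**Figure D3:**
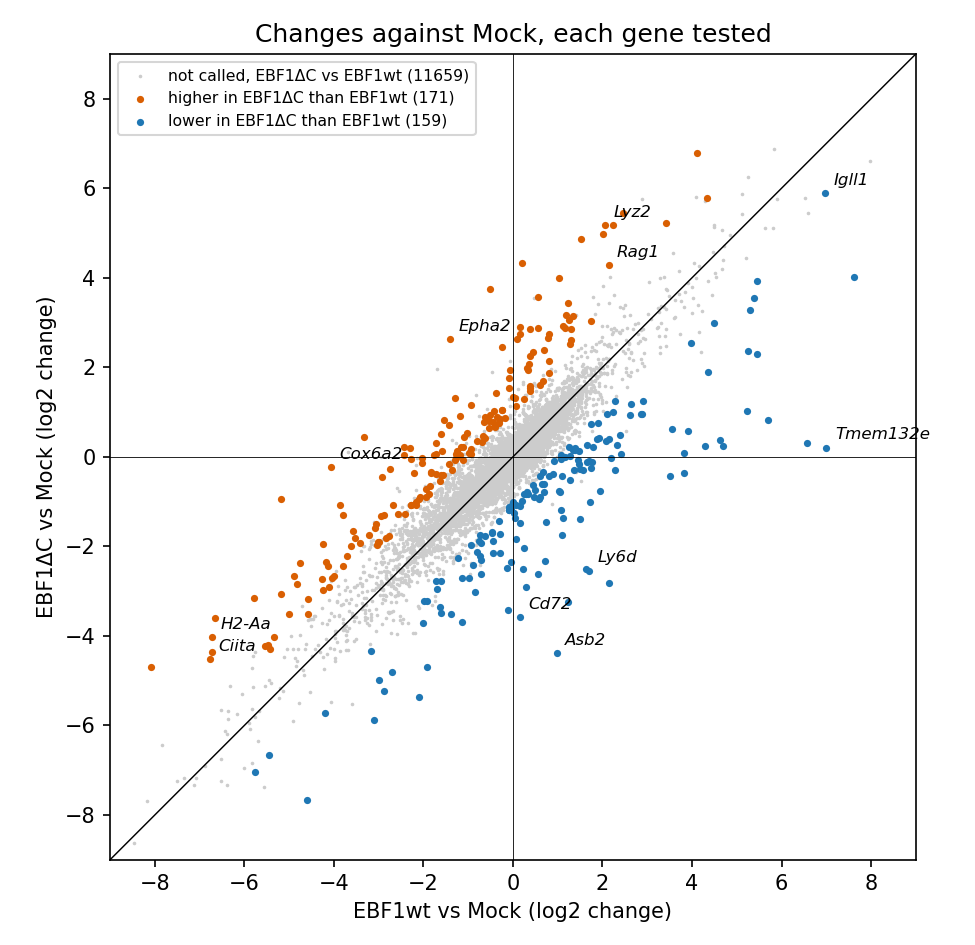
Log2 change against Mock of the 11989 genes tested, EBF1wt on the horizontal and EBF1ΔC on the vertical axis, with the line of equal change. Orange points are the 171 genes called higher and blue points the 159 called lower in EBF1ΔC than in EBF1wt.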

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

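The tests of mature B cells and of array scaling in the first pattern below, and both tests of the second, were chosen after the result was seen; the chromosome pattern was itself found in these data before its tests were set.

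Changes of EBF1wt and EBF1ΔC against Mock were called in opposite directions for 7 genes, with the difference between EBF1ΔC and EBF1wt tested directly in limma. It was -4.95 log2 for Clic5, 4.04 for Epha2, 2.61 for Iigp1, -4.24 for Ly6d, -2.73 for Otub2, -2.83 for Rapgef3 and -4.14 for Slpi. Clic5 was 2.14 above Mock with EBF1wt and -2.81 with EBF1ΔC. These directions against Mock depend on the scaling. Scaling to the median raised the median change of all genes from 0.12 to 0.83 in EBF1wt and from 0.11 to 0.65 in EBF1ΔC. Such a shift would leave Iigp1 in EBF1wt (-1.3) and Otub2 in EBF1ΔC (-1.01) short of 2-fold below Mock. Epha2 was not well above background on any EBF1wt array, so its 4.04 stands for at least 6.82-fold and its fall against Mock for at least 1.1-fold, which does not establish opposite directions. Among 2381 probes without a gene name, which no comparison used, 55 were called between EBF1ΔC and EBF1wt (50 higher), 1060 between EBF1wt and Mock (969 lower) and 973 between EBF1ΔC and Mock (868 lower). Of the genes tested, with 1 probe each, 2.75%, 19.4% and 18.1% were called in these comparisons. The filter also kept probes well above background on Mock arrays alone, and their part in the lower calls was not tested. No gene was tested for a value confined to 1 array, since a group of 3 is too small for it; EBF1wt replicate 2 had the lowest array weight (0.372).

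The splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split came first (1 of 10) with 330 genes between EBF1ΔC and EBF1wt, where the highest other gave 4, and with 2322 and 2165 against Mock, where the highest other gave 0. For genes differing among the 3 groups by the moderated F test, 1 of 100 splits, the real one, reached 8427. The highest other gave 6991. A share of 1 in 100 is the smallest that 100 splits can give, so it argues against chance without excluding it. The F test covers the 3 groups at once and does not decide the split between EBF1ΔC and EBF1wt. Mock arrays shared a scan day and slides with no other group, so the share does not separate treatment from these.

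Mature B cell genes were higher in Mock than in both replaced groups. Array scaling as the cause is argued against, since under 4 other scalings the list median stayed between -2.25 and -1.36 with a camera adjusted p of at most 1.37e-08. Mature B cells in the Mock cultures remain possible: 13 of the 23 list members on the array (56.5%) were well above background on all 3 Mock arrays and called lower in both other groups, between the bounds set for and against. Another cell line in the Mock cultures is also open, since 0 of 5 sex-linked genes differed 4-fold but lines of one sex would look alike. Scan day, slide, time after tamoxifen, and a biological effect of lost EBF1, which was not tested apart, cannot be told apart from one another.

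Interferon response and mature B cell genes were higher in EBF1ΔC than in EBF1wt. Within the 2 slides holding both groups the medians of both lists were 0.21 to 0.75, from 1 array per group on each slide. A difference between slides cannot produce these values. The same arrays helped to pick the lists, however, so slide as the cause is argued against only in part. A single EBF1wt array is argued against as well, since without each in turn the medians were 0.26 to 0.58 and the highest camera adjusted p was 0.000743. The absence of the C-terminal domain may underlie the difference, as a hypothesis, but no call held with an estimated correlation (adjusted p = 0.127 for both lists), and a difference in EBF1 level was not tested for these lists.

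Genes on chromosome 6 were higher and 4 Y-linked genes lower in Mock than in both replaced groups, a pattern found by looking through 21 chromosomes in 3 comparisons. The 560 genes of chromosome 6 had medians of -0.29 and -0.28 relative to all genes (adjusted permutation p = 0.001 each; the unadjusted 1e-04 is the smallest that 10000 draws can give), and chromosome 7 also passed (medians -0.11 and -0.09, adjusted p = 0.001 each), as did chromosomes 2 (0.08 and 0.07, 0.0077 and 0.01), 18 (0.16 and 0.15, 0.0079 and 0.0028) and, in EBF1wt, X (0.13, 0.0097). The draws took random sets of genes and left the arrays in place. These p-values therefore ignore the spread between arrays and the correlation between genes, and both comparisons share the same Mock arrays. The 7 genes whose probes the files place on Y had medians of 0.96 and 0.95 (adjusted permutation p = 0.05 and 0.046). Among them Zfy2 (0.45 and 0.72 against Mock), Atp5k (0.33 and 0.41) and Zfy1 (0.16 and 0.32) changed least. Ddx3y, Eif2s3y, Kdm5d and Uty were 1.06 to 1.90 above Mock, with Uty well above background on only 1 Mock array. Array scaling is argued against for these 4 genes, which stayed 0.79 to 1.34 above all genes under 4 other scalings, whereas the chromosome 6 medians shrank to -0.18 with the authors' values and may depend in part on the processing. Fewer Y chromosomes in Mock stay open, since the medians of 7 other probes placed on Y lay 0.11 and 0.39 above that of all probes, and so does a different number of chromosome 6, since the 8 windows of 20 Mb ran from -0.42 to -0.06, all below 0, with 1 window short of the bound set and other chromosomes shifted too.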

How the results depend on the processing

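The random slide block and the restriction to genes well above background were chosen after the data were seen; the other alternatives were planned and all of them were run. For values not explained by fewer genes or arrays or by the threshold itself, the cause was not tested. Signal over background limits dim genes, whose log2 changes shrink when an offset is added.

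Genes called between EBF1ΔC and EBF1wt, EBF1wt and Mock, and EBF1ΔC and Mock numbered 129, 1029 and 1038 with normexp and quantile normalization, 125, 1006 and 1011 with the authors' values, and 218, 1488 and 1423 among genes well above background on all 9 arrays. They numbered 5350 and 3923 against Mock with median scaling, and 1093, 7972 and 7723 with no minimum fold. EBF1ΔC against EBF1wt gave 208 with only these 2 groups, 146 with slide as a block, 181 at an adjusted p under 0.01 and 111 with treat against 1.5-fold. With the random slide block it gave 332, and 310 among genes well above background. The labels do not say whether replicate numbers pair samples, and residuals of equal numbers correlated at -0.18 to 0.12. Blocking on the numbers gave 280, 2320 and 2152. Leaving out each array gave 248 to 359, 2147 to 2355 and 2016 to 2231, and 7267 to 8438 for the F test.

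Higher genes lower in EBF1ΔC and lower genes higher in it numbered 36 and 24 (normexp), 35 and 25 (authors), 125 and 61 (median), 45 and 61 (all 9 arrays), 40 and 51 (slide block), 345 and 289 (no minimum fold) and 38 and 31 (treat). The second count was 57 with only 2 groups and 52 at the stricter threshold. Without each array they were 62 to 77 and 68 to 117. The ratios of summed changes were 0.84 and 0.93 (normexp and authors), 0.89 and 0.91 (quantile) and 0.83 and 0.93 (median). The first was 0.86 with no filter, all 9 arrays, the stricter threshold and treat, 0.89 with no minimum fold and 0.85 among genes well above background, and the second 0.92 with array weights. Leaving out each array gave 0.85 to 0.88 and 0.86 to 0.92.

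Lists past the threshold numbered 0, 1 and 1 with an estimated correlation. For EBF1wt against Mock they numbered 7 with normexp, quantile, authors' values and all 9 arrays, and 18 with fry, which gave 16 for EBF1ΔC against Mock. Without each array they numbered 6 to 9, 9 to 11 and 6. The Ebf1 clone probe against Mock gave -0.87 and -0.90 with normexp and -0.74 and -0.77 with the authors' values, short of the call. Leaving out each array, the mRNA probe gave 0.64 to 0.79, 1.47 to 1.75 and 2.21 to 2.49, and the clone probe -0.82 to 0.04, -3.83 to -3.46 and -4.44 to -3.57.

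Called values that changed sign were Pltp between EBF1ΔC and EBF1wt (-0.12, authors' values), the erythroid list between EBF1wt and Mock (0.53, all 9 arrays), and, with the mean of the probes, Ebf1 against Mock (-1.0 and -0.76) and Tyms between EBF1ΔC and Mock (-0.13). Values that were not called changed sign more often, at most in 7 list results and 6 gene results per setting, both with median scaling. Of the other named genes and lists, 7210 values kept their side of the threshold, 317 lost the call and 55 gained it. For comparisons with Mock the slide block in this tally was random, since Mock slides held no other group and a fixed block cannot be estimated there.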

Other observations

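Across 14 gene families looked through after seeing the data, guanylate-binding proteins and immunity-related GTPases, which act in interferon-induced defence, had the lowest camera p between EBF1ΔC and EBF1wt: 4 of 14 members were called higher, Iigp1 (2.61), Tgtp1 (1.46), Gbp2b (1.45) and Gbp2 (1.24), with a camera adjusted p of 2.66e-08, and adjusted p = 0.51 with an estimated correlation. Chemokines and their receptors had 2 of 14 higher, Ccl6 (1.82) and Ccr9 (1.42), at 0.00453, and adjusted p = 0.51 estimated. Aminoacyl-tRNA synthetases were lower as a family (median -0.16, 0.00317, and adjusted p = 0.51 estimated) with 0 of 34 called, and histones were higher (median 0.14, 0.0467, and adjusted p = 0.629 estimated) with 0 of 37 called.

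Between EBF1wt and Mock, the integrin family had 11 of 19 members lower and 0 higher, Itgal (-3.52) and Itgax (at least 31.5-fold lower) among them, at a camera adjusted p of 0.00642, and adjusted p = 0.226 estimated. Families were taken by gene symbol, so the 11 include Itgb1bp2 (-1.86), an integrin-binding protein. Chemokine genes had 7 of 14 lower, with Ccr6 (-5.83) and Ccr2 (-5.81), and 1 higher, Cxcr4 (2.30), at 0.0128, and adjusted p = 0.337 estimated. Proteasome subunits (2 of 37 called, median 0.49) and respiratory chain genes (2 of 84 higher and 1 lower, median 0.41) were higher as families at 5.09e-06 each, and adjusted p = 0.337 and 0.348 estimated. Aminoacyl-tRNA synthetases were higher (5 of 34 called, 0.000371, and adjusted p = 0.337 estimated), and guanylate-binding proteins and related GTPases lower (3 of 14 lower and 1 higher, 0.00263, and adjusted p = 0.366 estimated). Between EBF1ΔC and Mock, proteasome (2.14e-06, and adjusted p = 0.435 estimated), respiratory chain (1.29e-07, and adjusted p = 0.435 estimated) and synthetase genes (0.0193, and adjusted p = 0.47 estimated) were higher and the integrin family lower (7 of 19, Itgb1bp2 among them, 0.0225, and adjusted p = 0.354 estimated).

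A smaller response to EBF1ΔC than to EBF1wt was examined as a pattern as well and set aside for the chromosome pattern once that was seen. The within-slide ratios were at most 0.924 and the ratios on held-out EBF1wt arrays 0.845 to 0.999; neither measures the amount of EBF1, and the cause was left open. The simulation behind the expected overlap was corrected once, to include the error of the group means, which moved its mean for lower genes from 0 to 0.01. The bound of 4-fold for sex-linked genes was set before they were seen and was not met, though all 4 Y-linked genes it covered differed at least 2-fold. Zfy2 (0.45 and 0.72 log2 against Mock in EBF1wt and EBF1ΔC) and Zfy1 (0.16 and 0.32), which it did not cover, stayed short of 2-fold.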
